A study of Homo sapiens with 10 samples.

How the data were processed

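Total RNA was measured by sequencing in vesicle preparations of 8 established human breast cancer lines, in 10 libraries. Per the labels' protocols, cells grew with 1% serum cleared of vesicles, medium was collected at 72, 96 and 120 h after seeding, and vesicles were isolated from the combined medium by size exclusion chromatography. Insulin at 10 ug/mL was added for MCF7, T47D and BT483 only, the lines that are both ER-positive and HER2-negative; BT474 is ER-positive and had none added. Per the labels, RNA was treated with DNase, 10 ng entered each library, ribosomal RNA was depleted with a commercial reagent, and a directional kit was followed by 15 and then 9 cycles of PCR. The submitters' processing notes name bcl2fastq 2.16, HISAT2 2.1.0, DESeq2 and the build GRCh38/hg38. The counting tool, the annotation release, the strand setting and the handling of PCR duplicates are not given in the sources used here. With 24 PCR cycles and no molecular identifiers named, reads are not independent molecules, so the intervals and floors printed here cover counting error only. The counting strand being unknown, antisense and overlapping genes are uncertain, as are near-identical copies such as the 7SL, histone and ribosomal protein genes and their pseudogenes.

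The deposited table holds raw counts per gene, whole numbers with no normalization, and a gene length in bases that the authors gave with it. Of its 60706 rows, 202 repeated a gene identifier with the same counts and were dropped, which left 60504 genes. The table gave a symbol for 37883 of them; 19115 were named from the reference by identifier and 3506 kept their identifier. Coordinates come from GENCODE release 29 on GRCh38, matched by identifier for 56996 genes. Total counts ran from 299924 (T47D) to 2597107 (pooled BT483); MCF7 had 541384, HCC1143 717905, SKBR3 959689, pooled BT474 1092774, MDAMB231 1168208, HS578T 1325905, single BT474 1797724 and single BT483 2473722. A count of 0 was read as an upper limit of 3 counts of the total.

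Groups were taken from the subtype label of each sample. The ER comparison set 4 lines against 4, the TNBC comparison 3 against 5, and the HER2 comparison 2 against 6 with ER status as a term, each with the pooled library of the 8 lines, so that the line is the replicate. BT474 was compared with BT483 in their 4 libraries. The main test was edgeR 4.0.16 (R 4.3.3): TMM factors, the default filter of filterByExpr, a quasi-likelihood fit and Benjamini-Hochberg adjustment at 0.05. Printed standard errors are the fitted log2 fold change divided by the square root of the test's F value, and CPM are computed from the total counts. The biological coefficient of variation was 0.623, 0.652 and 0.705 in the ER, TNBC and HER2 fits, and 0.0922 between BT474 and BT483. The fits were tested on simulated data with real means and library sizes. Genes were drawn independently at the trended dispersion, with the same proportions in every library apart from the planted changes. The spread of T47D and MCF7 over silent genes and correlation between genes were left out, so recovery in the real data may be lower. With 100 genes changed at each size, a log2 change of 4 was recovered for 87% of genes in the ER design, 89% in the TNBC design, 53% in the HER2 design and 100% between BT474 and BT483. A log2 change of 2 was recovered for 19%, 13%, 6% and 88%.

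A set of 30 gene lists was written before the data were examined, as were the main tests, the alternatives listed as such below and the rule for named genes; the tests of explanations came later. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with the adjusted p taken over lists, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance. Members are also counted adjusted over the list alone. Named genes are ESR1, PGR and ERBB2 in every library; the 6 largest fitted changes each way among genes past the threshold whose groups did not overlap and whose mean was above the median of tested genes (4 each way for BT474 against BT483); up to 3 members with the smallest adjusted p of lists that passed camera or held at least 2 members past the threshold; and, for library composition, the 10 genes with the largest mean share. Genes named outside the rule are GRB7, S100A4, ENSG00000218227, NET1, RAB13, S100A8, OLR1, IVL and ACTA1, which were chosen after their values were seen, and CYB5R3, DYNLL2 and PKP4, which were chosen for a test. Shares of 9 RNA classes were compared by ER status with two-sided exact permutation tests (SciPy 1.17.1, Python 3.11.15). Library agreement was measured on log2(CPM + 1) over genes with a mean of at least 10 counts.

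The rate over 350 olfactory receptor genes, and over 157 KRTAP, TAS2R and DEFB genes as a second silent class, was taken as CPM per kb of the deposited gene length. Both classes were chosen by name and assumed to be silent, which was not checked. Expression of some members would raise the rates and the background estimated from them. Alternatives listed before the data were examined covered DESeq2 size factors, upper-quartile factors, DESeq2 1.42.0 (Wald test), no count filter and a stricter one, both libraries of a line summed, single in place of pooled libraries, limma-voom over the 10 libraries with the line as a random block, abundant and small RNA genes left out, a robust fit, HER2 status as a term or ER status left out, and each library left out in turn. Leaving out T47D and MCF7, thinning to the smallest total and the olfactory receptor rate as a term were added after seeing the data. Cell libraries and other data types of the study were not analysed here.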

Results

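Total RNA of extracellular vesicles (EVs), the membrane-bound particles that cells release into their medium, was sequenced from 8 established breast cancer lines. The series asks how the content of vesicles relates to that of the cells they come from; cell libraries were not analysed here, so the comparisons below are between vesicle libraries of different lines. The labels give 4 lines as positive for the estrogen receptor (ER): BT474, T47D, MCF7 and BT483. HS578T, MDAMB231, SKBR3 and HCC1143 are labelled ER-negative. BT474 and SKBR3 are labelled positive for the receptor tyrosine kinase HER2, and HS578T, MDAMB231 and HCC1143 are labelled triple negative (TNBC), lacking ER, the progesterone receptor and HER2. Each line had 1 library named as a pooled replicate, and BT474 and BT483 each had a further library named as a single replicate, which made 10 libraries. Total counts ranged from 299924 in T47D to 2597107 in the pooled BT483 library, an 8.66-fold range. A gene with no count could therefore lie anywhere up to 10.0 CPM (counts scaled to a library total of 1e6) in T47D and 1.16 CPM in the pooled BT483 library, at 3 counts of the total.

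The signal recognition particle RNA RN7SL2 (ENSG00000274012, chromosome 14, 49862550 to 49862849, GRCh38) was the most abundant gene, with a mean share of 4.25% of counts over the 10 libraries and a range from 1.69% (95% Wilson interval 1.67 to 1.72) in pooled BT474 to 7.99% (7.92 to 8.07) in MCF7. 7SK, a nuclear RNA that restrains transcription elongation, followed at 0.845%, and the 7SL copies RN7SL5P and RN7SL4P at 0.816% and 0.602%. These 7SL genes are near-identical, so the division of reads among them is uncertain. By the same mean, the most abundant mRNAs were those of ferritin heavy chain (FTH1, 0.825%), beta-actin (ACTB, 0.816%), the ribosomal protein RPL19 (0.629%), the kinesin KIF1C (0.532%), the motor adaptor TRAK2 (0.500%) and GAPDH (0.491%). With each line counted once, over the 8 pooled libraries, the 10 genes were the same but their order was not: ACTB (0.799%) stood above FTH1 (0.749%), KIF1C (0.597%) above RPL19 (0.562%), and RN7SL5P (0.829%) above 7SK (0.786%). TRAK2 ranged from 0.0550% (0.0505 to 0.0599) in SKBR3 to 2.12% (2.1 to 2.15) in HS578T, and RPL19 from 0.0583% (0.0503 to 0.0677) in T47D to 1.92% (1.89 to 1.94) in pooled BT474. All 13 mitochondrial mRNAs and both mitochondrial rRNAs had 0 counts in the 10 libraries, so the lists of these genes gave no test; whether they were removed before deposit is not given in the sources used here.

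Protein-coding genes took 81.7% ± 8.39 of counts in ER-positive lines and 87.4% ± 2.62 in ER-negative lines (SD, n = 4 each). Ribosomal protein mRNAs took 3.81% ± 2.01 and 6.45% ± 1.93, and 7SK 0.939% ± 0.252 and 0.633% ± 0.197. None of the 9 RNA classes passed a two-sided exact permutation test after adjustment over classes. The smallest unadjusted exact p was 0.0286 for 7SK, the smallest that 4 against 4 lines can give, with an adjusted value of 0.257. A single class could therefore not pass, however far apart its groups lay, and the absence of calls says little. T47D and MCF7 stood apart from the other libraries. Long non-coding genes held 11.2% (95% Wilson interval 11.1 to 11.3) of their counts in T47D and 9.29% (9.22 to 9.37) in MCF7, and 1.29% to 3.97% in the other 8 libraries. At the smallest totals they had counts in the largest numbers of genes, 36390 and 38960. Olfactory receptor genes, assumed here to be silent in breast lines, received 2.61 CPM per kb in T47D (95% Poisson interval 2.32 to 2.93) and 1.45 (1.29 to 1.63) in MCF7. The other libraries lay between 0.0763 in HS578T and 0.768 in pooled BT474. Both lines belong to the ER-positive group, so this difference stands beside every ER comparison below.

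**Figure D1:**
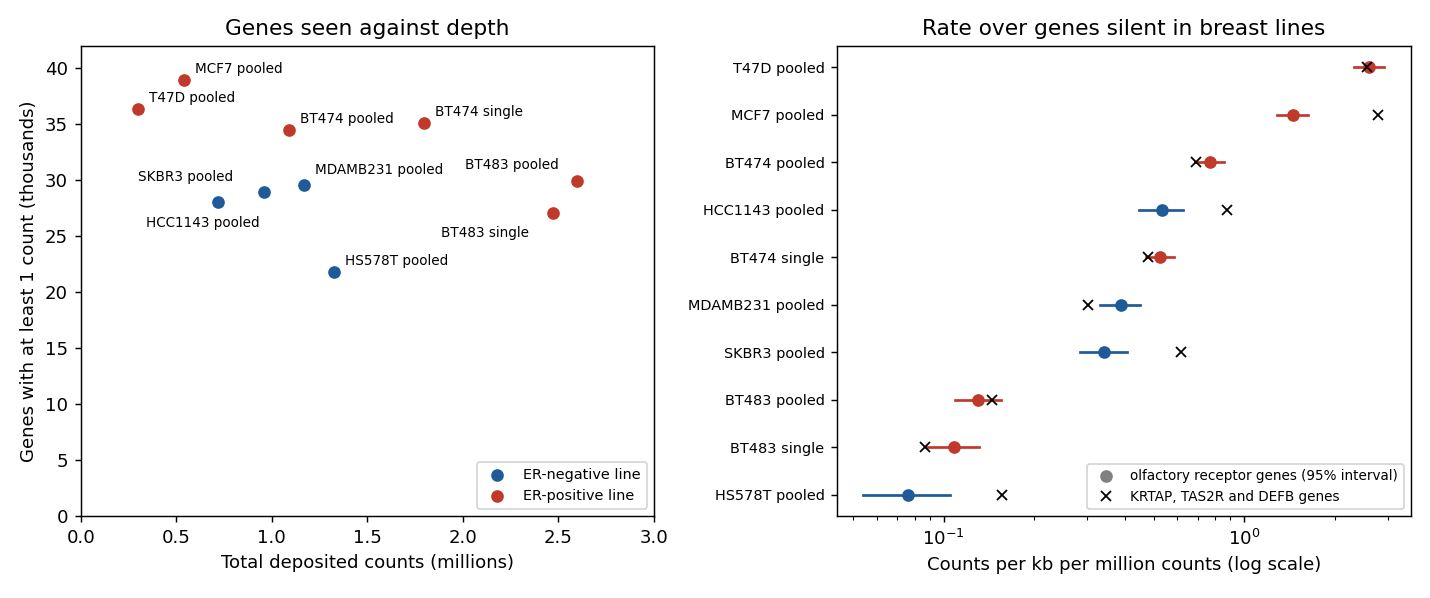
Left, genes with at least 1 count against total counts for each of the 10 libraries, in red for ER-positive and blue for ER-negative lines. Right, CPM per kb (log axis) over olfactory receptor genes, with 95% Poisson intervals, and over a second silent class (KRTAP, TAS2R and DEFB genes, crosses); T47D at 2.61 and MCF7 at 1.45 lie above the other libraries.

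The receptor genes were read in every library as a check of the labels. The ER gene ESR1 (ENSG00000091831, chromosome 6, 151656691 to 152129619) lay at 39.3 to 77.6 CPM in the 6 ER-positive libraries and at 1.51 to 13.9 CPM in the 4 ER-negative ones. For T47D this rested on 16 counts, against 10.7 counts that its rate over olfactory receptor genes would give over the length of ESR1. The progesterone receptor gene PGR (ENSG00000082175, chromosome 11, 101029624 to 101130524) lay at 31.2 to 395 CPM in ER-positive and 1.39 to 11.5 CPM in ER-negative libraries. MCF7, labelled negative for the progesterone receptor, had 64.6 CPM of PGR, within the range of the lines labelled positive. This rested on 35 counts, against 12.1 counts that its olfactory receptor rate would give over the length of PGR. The MCF7 rate over the second silent class was higher, at 2.78 against 1.45 CPM per kb, so part of this value may be background. ERBB2, which encodes HER2 (ENSG00000141736, chromosome 17, 39687914 to 39730426), lay at 1730 CPM and 2030 CPM in the BT474 libraries and at 2870 CPM in SKBR3, and at 18.9 to 172 CPM in the libraries labelled HER2-negative.

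Libraries of a line resembled each other more than libraries of different lines. Across genes with a mean of at least 10 counts, the log2 ratio between both BT474 libraries had an SD of 0.46 over 12019 genes, with Pearson's r = 0.959. For BT483 the SD was 0.32 over 12247 genes, with r = 0.982. The 43 pairs of different lines had SDs from 0.69, between T47D and MCF7, to 2.06, and r from 0.157 to 0.757. These correlations are across genes, which are not independent replicates. The chi-square per degree of freedom between libraries of a line was 3.31 for BT474 and 1.64 for BT483; it is set against counting error only and takes reads as independent, so an excess over 1 does not set PCR apart from other differences. The labels do not say whether they came from separate cultures.

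TFF1, TFF3 and PGR were among the genes higher in vesicles of ER-positive lines, and FN1, CAV1 and NT5E among those higher in vesicles of ER-negative lines. TFF1 (ENSG00000160182, chromosome 21, 42362282 to 42366594), a secreted trefoil peptide and a classical estrogen target, was at 311 ± 333 CPM in ER-positive and 0.475 ± 0.553 CPM in ER-negative lines (SD, n = 4 each), with a log2 fold change of 8.89 ± 1.29 (SE) and an adjusted p of 0.0407 in edgeR's quasi-likelihood test. The ER-negative value rested on 2 counts. The ratio of summed counts, scaled to the total counts of each group, was 1110 with a counting interval of 308 to 9200. Its neighbour TFF3 (chromosome 21, 42311667 to 42315651) was higher by 6.30 ± 1.00 on the log2 scale. PGR was higher by 4.63 ± 0.86, at 160 ± 145 against 5.49 ± 4.64 CPM. The antisense transcript TM4SF18-AS1 (ENSG00000244468, chromosome 3, 149284782 to 149333653) was higher by 7.65 ± 1.15; the counting strand is not given in the sources used here, so reads of overlapping genes on the opposite strand cannot be set apart. The homeobox gene LMX1B and the calcium channel gene CACNA1H were higher by 5.0 ± 0.93 and 4.41 ± 0.82. In the other direction, fibronectin (FN1, ENSG00000115414, chromosome 2, 215360440 to 215436172) was at 42 ± 22.5 CPM in ER-positive and 2230 ± 2180 CPM in ER-negative lines, a log2 fold change of -6.15 ± 1.12. The long non-coding RNA LINC03061 differed by -6.61 ± 1.24, the caveolar gene CAV1 by -5.42 ± 0.85, and NT5E, which encodes the surface nucleotidase CD73, by -4.86 ± 0.79. The coagulation factor gene F3 and the matricellular gene CCN2 differed by -4.34 ± 0.72 and -4.20 ± 0.76. These genes had adjusted p between 0.0407 and 0.0489 in the same test. Of 11595 genes tested, 33 passed the threshold, 23 higher and 10 lower in ER-positive lines, and 2160 had an unadjusted p under 0.05. The adjusted p of the 33 genes lay between 0.0407 and 0.0489, and the count hung on single lines: it was 0 without HS578T, MCF7, MDAMB231 or HCC1143, 1 without T47D, 6 without BT474, 57 without BT483 and 108 without SKBR3. Without both T47D and MCF7, an alternative chosen after seeing the data, 2 genes passed, TFF1 and TM4SF18-AS1. Each of the 33 genes kept its own direction of the main fit in these refits, which their choice from a fit that held the remaining libraries favours. Upper-quartile scaling gave 20 higher and 4 lower, DESeq2 gave 228 higher and 389 lower, and limma-voom over the 10 libraries gave 0 higher and 6 lower.

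Among the gene lists fixed beforehand, the estrogen response list was the one with most genes past the threshold in the ER comparison. Of its 25 tested members, 6 were higher, 0 were lower and 19 did not pass; adjusted over the list alone, 7 were higher and 2 lower. Besides TFF1, TFF3 and PGR they included OLFM1, at 88.7 ± 49.9 CPM in ER-positive and 4.84 ± 2.66 CPM in ER-negative lines. The list's adjusted p in camera was 3.43e-06 with a preset correlation of 0.01, and its adjusted p was 0.247 with an estimated correlation. Of 23 luminal genes, which mark the hormone-responsive epithelium, PGR alone passed, and 5 were higher adjusted over the list alone (camera adjusted p = 7.67e-07, and adjusted p = 0.248 with an estimated correlation). GATA3, the luminal transcription factor, had 649 ± 725 CPM against 49.7 ± 53.1 CPM and did not pass, with an edgeR adjusted p of 0.107. ESR1 itself had a log2 fold change of 2.83 ± 0.60 and an edgeR adjusted p of 0.0664. Of 36 mesenchymal genes, 3 were lower in ER-positive lines (FN1, CCN2 and the hyaluronan receptor gene CD44) and 18 were lower adjusted over the list alone. CD44 lay at 43.2 ± 18.8 CPM in ER-positive and 257 ± 61.7 CPM in ER-negative lines. The list's camera adjusted p was 6.61e-14, and its adjusted p was 0.248 with an estimated correlation. Of 20 basal genes, CAV1 and CAV2 were lower and 18 did not pass (camera adjusted p = 0.00579, and adjusted p = 0.384 with an estimated correlation). EGFR, the epidermal growth factor receptor gene, had 39.2 ± 24.0 against 345 ± 259 CPM and did not pass. T47D and MCF7, with their high rate over silent genes, lay in the ER-positive group throughout. Without both, in a refit chosen after seeing the data, the lists of this paragraph kept their camera direction and call. The camera adjusted p with the preset correlation was 1.43e-11 for estrogen response, 2.73e-11 for luminal, 3.57e-20 for mesenchymal and 0.0286 for basal genes. An estimated correlation was not run in that refit.

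Lists of housekeeping and stress genes leaned lower in ER-positive lines in camera, with few members past the threshold. Of 78 ribosomal protein genes none passed, and the median log2 fold change was -1.19 (camera adjusted p = 2.74e-15, and adjusted p = 0.369 with an estimated correlation). RPS23 lay at 194 ± 27.0 CPM in ER-positive and 554 ± 221 CPM in ER-negative lines. For 29 translation factor genes, of which none passed, the median was -0.77 (camera adjusted p = 3.43e-06, and adjusted p = 0.369 with an estimated correlation); EIF3A, a subunit of the initiation factor eIF3, lay at 238 ± 56.4 and 619 ± 159 CPM. Of 9 antigen presentation genes, beta-2-microglobulin (B2M) was lower, at 39.6 ± 17.8 against 403 ± 299 CPM, and 7 were lower adjusted over the list alone (camera adjusted p = 7.61e-06, and adjusted p = 0.247 with an estimated correlation). CALR, the chaperone calreticulin, had 123 ± 25.5 and 390 ± 54.6 CPM and an edgeR adjusted p of 0.107. Of 22 hypoxia and glycolysis genes none passed, and 6 were lower adjusted over the list alone (camera adjusted p = 0.00161, and adjusted p = 0.247 with an estimated correlation); DDIT4 lay at 56.4 ± 15.7 against 285 ± 159 CPM. Unfolded-protein genes, with 2 of 20 lower adjusted over the list alone, had a camera adjusted p of 0.00187 and an adjusted p of 0.248 with an estimated correlation. The histone list of 46 genes had a camera adjusted p of 0.00255 and an adjusted p of 0.527 with an estimated correlation, with none past the threshold. Genes of vesicle formation, 31 in number, also had none past the threshold, with a camera adjusted p of 0.0229 and an adjusted p of 0.605 with an estimated correlation; CD151, a tetraspanin, lay at 57.6 ± 34.0 against 154 ± 90.8 CPM. Without T47D and MCF7 this list turned upward (camera adjusted p = 0.7). Other lists that passed camera also lost the call with an estimated correlation: epithelial junction genes, higher, with 28 tested (camera adjusted p = 0.001, and adjusted p = 0.605 with an estimated correlation), and, lower, the lists of ERBB and MAPK feedback, NF-kB, proliferation, integrin and cholesterol genes (camera adjusted p from 0.000268 to 0.0428, and adjusted p from 0.248 to 0.646 with an estimated correlation). Apart from vesicle formation, proliferation and cholesterol genes, the lists of this paragraph kept direction and call without T47D and MCF7. Their camera adjusted p ran from 4.21e-09 (ribosomal protein) to 0.0402 (hypoxia). The 17q12 list, higher, and the interferon list, lower, gained a call in that refit (camera adjusted p = 0.00225 and 0.0434). The proliferation and cholesterol calls ended (camera adjusted p = 0.769 and 0.241). Calls also ended for basal genes without HCC1143 (0.81) or BT474 (0.189), for epithelial junction and histone genes without HS578T (0.228 and 0.119), and for integrin genes without SKBR3 (0.104). In all, camera with the preset correlation passed 17 lists in the ER comparison, and 0 passed with an estimated correlation or in fry.

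**Figure D2:**
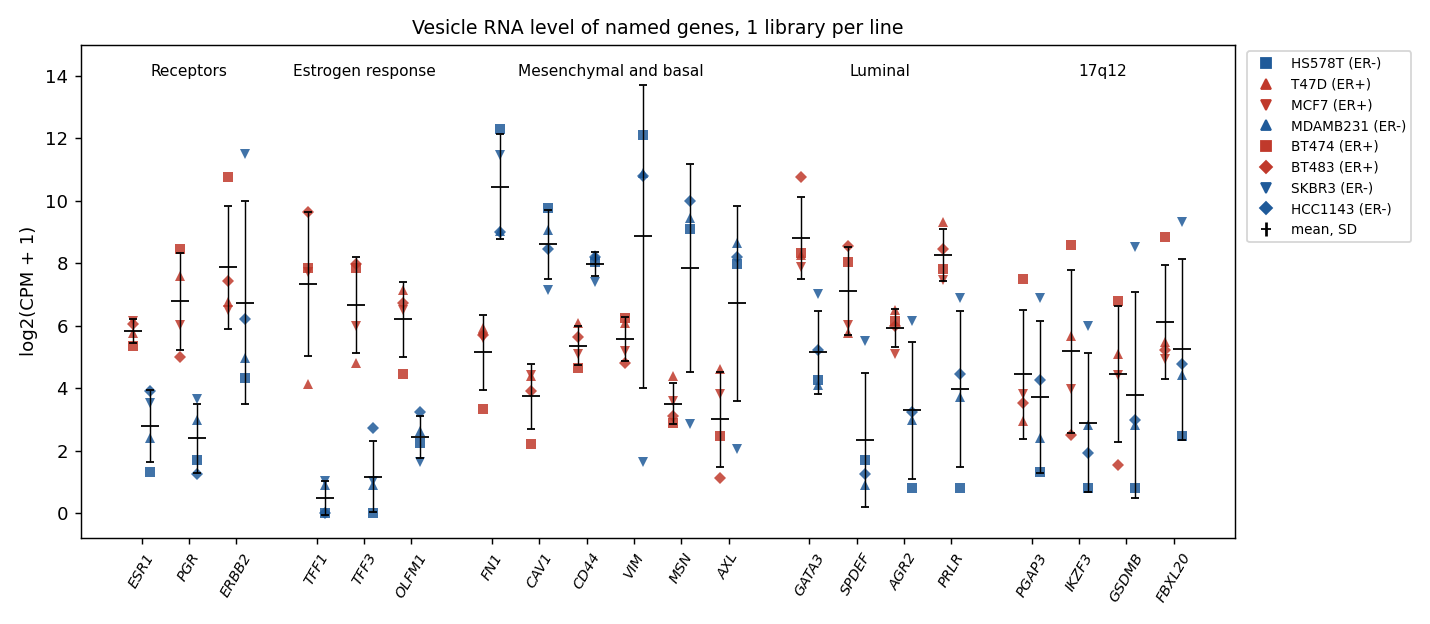
Level of named genes as log2(CPM + 1) in 1 pooled library of each line; each symbol is a line, red for ER-positive and blue for ER-negative, and black bars give the mean and SD of the 4 lines of a class. TFF1 lies at 16.7 CPM or more in the ER-positive lines and at 1.04 CPM or less in the ER-negative ones, and SKBR3 lies within or below the range of the ER-positive lines for VIM, MSN and AXL.

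The comparison of the 3 TNBC lines with the other 5 differs from the ER comparison in the side of 1 line, SKBR3. MSN, VIM and ZEB1 were among the genes higher in TNBC vesicles, and CACNG4 and SPDEF among those lower. Moesin (MSN, ENSG00000147065, chromosome X, 65588377 to 65741931), which links membrane to actin, lay at 751 ± 241 CPM in TNBC (SD, n = 3) and 10.3 ± 5.77 CPM in the other lines (SD, n = 5), a log2 fold change of 6.57 ± 0.65 (SE) with an adjusted p of 0.000934 in edgeR's quasi-likelihood test. Vimentin (VIM, ENSG00000026025, chromosome 10, 17228259 to 17237593) lay at 2690 ± 1460 against 41.0 ± 29.6 CPM, a log2 fold change of 6.55 ± 0.98. The transcription factor gene ZEB1 (chromosome 10, 31318495 to 31529814), which represses epithelial genes, was higher by 7.65 ± 1.23 with an edgeR adjusted p of 0.0201. The receptor tyrosine kinase gene AXL, the glutathione transferase gene GSTP1 and LINC03061 were higher by 5.76 ± 0.78, 6.22 ± 0.85 and 6.50 ± 0.90. In TNBC the channel subunit gene CACNG4 (ENSG00000075461, chromosome 17, 66964910 to 67033398) lay at 0.788 ± 0.756 CPM, from 3 counts in all, and in the others at 210 ± 145 CPM. The ratio of summed counts, scaled to the total counts of each group, was 322 with a counting interval of 110 to 1560. The ETS factor gene SPDEF differed by -6.35 ± 1.14, at 1.5 ± 0.71 against 160 ± 150 CPM. BCAS1, SYTL2, the iron exporter gene SLC40A1 and the tetraspanin gene TSPAN13 differed by -5.16 ± 1.04, -4.92 ± 0.87, -4.89 ± 0.81 and -4.77 ± 0.87. Of 13407 genes tested, 56 passed, 32 higher and 24 lower in TNBC, and 2574 had an unadjusted p under 0.05. S100A4 and LINC03061 were the genes called in both this and the ER comparison. The count was 27 without HS578T, 28 without T47D, 31 without MCF7, 19 without BT474, 35 without BT483, 108 without SKBR3, 336 without HCC1143 and 16 without both T47D and MCF7. The balance of 32 higher and 24 lower moved too: it was 19 and 22 with upper-quartile scaling, 17 and 1 in limma-voom, 38 and 70 with a stricter filter, 25 and 2 without HS578T, and 52 and 5 without MDAMB231.

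Of 39 tested mesenchymal genes, 5 were higher in TNBC, 0 were lower and 34 did not pass, and 24 were higher adjusted over the list alone; the 5 included MSN, VIM and AXL (camera adjusted p = 1.82e-21, and adjusted p = 0.271 with an estimated correlation). Luminal genes went the other way: of 24 tested, SPDEF, the secretory protein gene AGR2 and the prolactin receptor gene PRLR were lower, and adjusted over the list alone 16 were lower and 1 higher (camera adjusted p = 1.04e-10, and adjusted p = 0.271 with an estimated correlation). AGR2 lay at 5.32 ± 4.03 CPM in TNBC and 64.9 ± 20.5 CPM in the other lines, and PRLR at 11.2 ± 10.1 and 301 ± 210 CPM. Among 28 epithelial junction genes, the transcription factor gene OVOL1 was lower, at 2.32 ± 1.39 against 42.6 ± 20.9 CPM, and 3 were lower adjusted over the list alone (camera adjusted p = 5.48e-11, and adjusted p = 0.419 with an estimated correlation). FOSL1, an AP-1 subunit, was higher, at 283 ± 117 against 13.1 ± 9.36 CPM; it was the 1 of 19 ERBB and MAPK feedback genes that passed over all genes, and 4 passed adjusted over the list alone (camera adjusted p = 2.5e-05, and adjusted p = 0.399 with an estimated correlation). Of 51 histone genes 1 passed, H3C8, which was lower, with 3 counts in TNBC. Its ratio of summed counts, scaled to the total counts of each group, was 44.7 (counting interval 15.1 to 218). Adjusted over the list alone, 13 histone genes were higher and 1 lower, and the camera direction was upward (adjusted p = 1.2e-08, and adjusted p = 0.399 with an estimated correlation). Estrogen response genes had 0 of 31 past the threshold, and adjusted over the list alone 11 lower and 1 higher (camera adjusted p = 8.81e-05, and adjusted p = 0.399 with an estimated correlation); CA12, a carbonic anhydrase gene, lay at 8.74 ± 7.10 against 84.5 ± 20.5 CPM. Proliferation genes had 0 of 32 past the threshold and 3 higher adjusted over the list alone (camera adjusted p = 6.36e-10, and adjusted p = 0.459 with an estimated correlation), with TYMS, thymidylate synthase, at 175 ± 16.2 against 34.2 ± 19.8 CPM. The 17q12 list had 0 of 19 past the threshold and 13 lower adjusted over the list alone (camera adjusted p = 1.03e-05, and adjusted p = 0.459 with an estimated correlation). Basal genes had 0 of 24 past the threshold, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0104, and adjusted p = 0.459 with an estimated correlation). The basal keratin gene KRT5 lay at 1.57 ± 0.920 CPM in TNBC and 19.4 ± 12 CPM in the others and did not pass. The olfactory receptor rate was 0.0763, 0.388 and 0.531 CPM per kb in the TNBC lines HS578T, MDAMB231 and HCC1143, and both high lines were in the other group. Ribosomal protein and translation factor genes leaned higher in TNBC with none of 78 and 30 past the threshold (camera adjusted p = 2.12e-13 and 9.58e-06, and adjusted p = 0.459 with an estimated correlation for both). The NF-kB and hypoxia lists passed camera as well (adjusted p = 0.0291 and 0.0283, and adjusted p = 0.459 with an estimated correlation for both). The hypoxia call ended without T47D and MCF7 (camera adjusted p = 0.33), the NF-kB call without BT483 (0.129), and the basal call without HCC1143 (0.781). The other lists kept direction and call without T47D and MCF7, with a camera adjusted p of at most 0.0173. Camera passed 13 lists here, and 0 passed with an estimated correlation or in fry.

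BT474 and SKBR3, compared with the 6 HER2-negative lines in a fit that also held ER status, shared a rise of genes around ERBB2. ERBB2 lay at 2300 ± 810 CPM in the HER2-positive lines (SD, n = 2) and 81.7 ± 55.7 CPM in the others (SD, n = 6), a log2 fold change of 5.22 ± 0.97 (SE) with an adjusted p of 0.0172 in edgeR's quasi-likelihood test. A further 8 genes of chromosome 17 within 1 Mb of ERBB2 passed, among them FBXL20 (39252644 to 39402523), PGAP3 (39671122 to 39696797), the adaptor gene GRB7 (39737927 to 39747291), the lymphoid transcription factor gene IKZF3 (39757715 to 39864188) and the gasdermin gene GSDMB (39904595 to 39919854). Their log2 fold changes were 4.6 ± 0.78 for FBXL20, 4.11 ± 0.68 for PGAP3, 4.45 ± 0.88 for GRB7, 4.45 ± 0.72 for IKZF3 and 5.08 ± 0.85 for GSDMB. FBXL20 rose from 26.8 ± 13.5 to 547 ± 129 CPM. Outside chromosome 17, the cell adhesion gene CEACAM6 (ENSG00000086548, chromosome 19, 41750977 to 41772208) was higher by 5.47 ± 0.85 and the dehydrogenase gene DHRS2 (ENSG00000100867, chromosome 14, 23630115 to 23645639) by 5.25 ± 0.80, both with an edgeR adjusted p of 0.00529. The last of the 12 genes, ENSG00000218227 (chromosome 5, 178055604 to 178056194), is annotated as a processed pseudogene. It shares 57.1% of its 25-base words with RPL19, which lies within 1 Mb of ERBB2, so its counts are uncertain. All 12 genes were higher in HER2-positive lines among 18054 tested, and 804 genes had an unadjusted p under 0.05. No gene was lower in the main edgeR fit. The robust edgeR fit gave 17 higher and 1 lower, the stricter filter 8 and 1, and thinning 13 and 1. DESeq2, run without the edgeR count filter, gave 43 higher and 16 lower. The count was 0 without T47D, 0 without MCF7, 7 without MDAMB231, 82 without BT474, 22 without BT483, 4 without SKBR3, 6 with HER2 status alone, and 0 without both T47D and MCF7 or in limma-voom over the 10 libraries. Leaving out BT474 or SKBR3 leaves 1 HER2-positive line, which is then assumed to vary like the other lines.

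**Figure D3:**
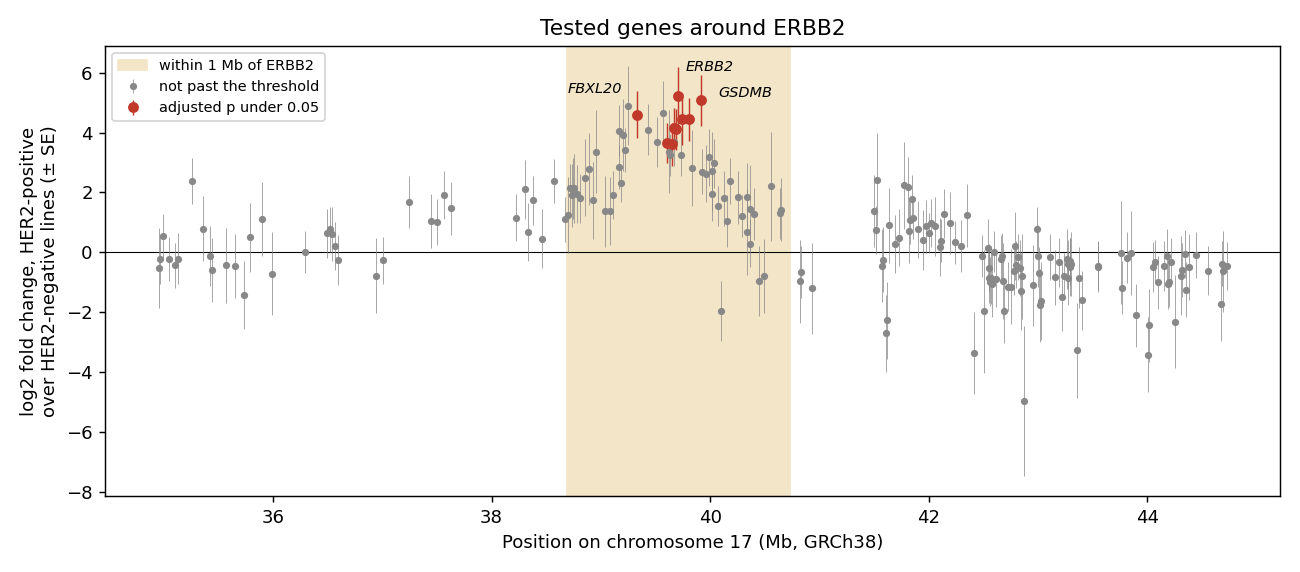
Log2 fold change (± SE) of each tested gene within 5 Mb of ERBB2, HER2-positive over HER2-negative lines, against its position on chromosome 17 (Mb, GRCh38); the shaded part lies within 1 Mb of ERBB2. The 9 genes past the threshold, in red, lie between FBXL20 and GSDMB.

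Of 19 tested genes of the 17q12 list, 9 were higher and 10 did not pass over all genes, and 18 were higher adjusted over the list alone, with a median log2 fold change of 3.67. The list passed camera with the preset correlation (adjusted p = 2.62e-82), with an estimated correlation (adjusted p = 0.000262) and in fry (adjusted p = 4.65e-05), and it is the 1 list of this comparison that passed in all of them. The other lists had no member past the threshold over all genes. Luminal genes had a median of 1.36 over 25 genes (camera adjusted p = 7.82e-12, and adjusted p = 0.196 with an estimated correlation), with the androgen receptor gene AR at 59.6 ± 60.7 against 14.4 ± 10.4 CPM. Epithelial junction genes had a median of 1.24 over 28 genes (camera adjusted p = 4.77e-17, and adjusted p = 0.355 with an estimated correlation). The mesenchymal list had a median of -1.58 over 40 genes, with 2 lower adjusted over the list alone (camera adjusted p = 1.92e-15, and adjusted p = 0.3 with an estimated correlation). LGALS1, galectin-1, lay at 14.1 ± 19.9 CPM in HER2-positive and 913 ± 1340 CPM in the other lines. Interferon response genes had a median of -1.07 over 35 genes (camera adjusted p = 1.12e-05, and adjusted p = 0.668 with an estimated correlation); MX1 lay at 5.87 ± 0.538 against 58.0 ± 41.2 CPM. Basal genes had a median of -1.08 over 29 genes (camera adjusted p = 0.000759, and adjusted p = 0.355 with an estimated correlation). Markers of fibroblasts, a cell type that a pure line should lack, had a median of -1.78 over 11 genes (camera adjusted p = 0.0145, and adjusted p = 0.686 with an estimated correlation). Without T47D and MCF7, 3 of these markers were tested and the call ended (camera adjusted p = 0.631); it also ended without HS578T alone (0.648) or SKBR3 alone (0.557). Cholesterol, nuclear long non-coding RNA and unfolded-protein genes leaned higher (camera adjusted p = 0.00265, 0.00544 and 0.0215, and adjusted p = 0.355, 0.196 and 0.686 with an estimated correlation). The cholesterol and unfolded-protein calls ended without T47D and MCF7 (camera adjusted p = 0.0996 and 0.209), the nuclear RNA call without BT474 (0.189), the epithelial junction call without SKBR3 (0.235) and the basal call without HCC1143 (0.0736), and the cholesterol list turned downward without BT474 (0.682). T47D and MCF7, high over silent genes, were both in the HER2-negative group. Without both, the 17q12 list kept its call (camera adjusted p = 1.24e-55). So did the luminal, epithelial junction, mesenchymal, interferon, basal and nuclear RNA lists (camera adjusted p from 1.78e-06 to 0.000981).

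BT474 and BT483 were the lines with 2 libraries each, and a direct comparison sets these libraries, not HER2 status, against each other. The vitamin B12 carrier gene TCN1 (chromosome 11, 59852800 to 59866575) was at 571 ± 68.3 CPM in BT474 (SD, n = 2) and had no count in BT483, at least 946-fold higher against 3 counts over both BT483 libraries. The mucin gene MUC6 and the lipoxygenase gene ALOX15B lay at 126 ± 32.7 and 143 ± 12.9 CPM in BT474, with 1 and 2 counts in BT483. The ratios of summed counts, scaled to the total counts of each line, were 610 (counting interval 109 to 24200) and 368 (101 to 3040). Glutathione peroxidase 1 (GPX1) lay at 123 ± 3.69 CPM in BT474, with 2 counts in BT483 and a ratio, scaled in the same way, of 310 (85.1 to 2570). BT483 in turn had 173 ± 11.3 CPM of LGALS1 and 79.3 ± 8.15 CPM of the synuclein gene SNCG, which had no count in BT474 and so lay at least 167-fold and 76.6-fold lower there. The antimicrobial genes S100A7 and S100A9 lay at 254 ± 38.6 and 244 ± 8.35 CPM in BT483 and at 1.11 ± 1.57 and 1.29 ± 0.533 CPM in BT474. ERBB2 was higher in BT474 by 3.50 ± 0.15 and PGR by 3.34 ± 0.16 on the log2 scale, and ESR1 differed by -0.81 ± 0.18, with an edgeR adjusted p of 0.000726. Of 13649 genes tested, 7997 passed in edgeR's quasi-likelihood test, 4009 higher and 3988 lower in BT474. DESeq2 gave 1289 higher and 3210 lower. The p-values measure the spread between libraries of a line, which may be technical.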

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

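Values that stand far from the other lines of their ER class were looked for in 258 groups of 4 lines, and 22 were found. Chance gives about 1 in 20 for items chosen without these data. The named genes were mostly chosen by comparisons of the same libraries, so that rate is no fair measure for them. MSN, VIM, GSTP1 and AXL were named because the TNBC lines did not overlap the others, which makes SKBR3 their low ER-negative line. The number after each gene or class is the gap to the nearest line divided by the range of the class, on log2(CPM + 1) for genes. In ER-negative lines SKBR3 was the low line for MSN (0.873, 6.25 CPM against 542 to 1010), VIM (0.877, 2.08 against 1790 to 4380), GSTP1 (0.913, 3.13 against 377 to 581), AXL (0.897, 3.13 against 250 to 400), TIMP1 (0.858), TYMS (0.89), NUSAP1 (0.846) and EIF3E (0.845). SKBR3 was the high line for NEUROD2 (0.877, 71.9 CPM against 2.57 to 4.18) and CALR (0.908, 472 CPM against 358 to 367). HCC1143 was the high line for CDH1 (0.867), at 123 CPM against 0.754 to 2.08, HS578T for MEG3 (0.836), and MDAMB231 for the pseudogene share (0.86) and, on the low side, the 7SK share (0.886). In ER-positive lines BT474 was low for FN1 (0.878), PHLDA1 (0.906) and KRT5 (0.91), and high for FBXL20 (0.862) and the 7SK share (0.926). BT483 was high for GATA3 (0.845, 1740 CPM against 236 to 322), T47D high for CA12 (0.93) and MCF7 low for HERPUD1 (0.835).

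An edgeR fit with a term for ER by HER2 status gave 7 of 21068 genes, but each ER class has 1 HER2-positive line, so the values below describe single lines and say nothing of HER2 status. S100A7 (log2 interaction -18.54), S100A8 (-15.84) and S100A9 (-14.86) had counts in BT483 (227, 27.3 and 250 CPM) and SKBR3 (54.2, 58.4 and 450 CPM), and at most 7.39 CPM in the other lines. IVL, a cornified envelope gene of keratinocytes, followed these lines too (-9.32, with 85.9 CPM in BT483 and 66.7 CPM in SKBR3). OLR1 (-12.45) and ACTA1 (-11.41) were high in SKBR3, at 223 and 104 CPM. GPX1 (16.72) had no count in the pooled libraries of BT483 and SKBR3 and 125 CPM in BT474. Several of the lines had no count of these genes, so the fitted sizes depend on the prior count and are no bounds. No explanation was tested for them.

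Of the tests below, the insulin test on BT474, the paralog share without the pseudogene, the forms of the pairs of lines and the thinned fit were chosen after the results were seen. In T47D and MCF7 counts were spread over many genes. Low depth is argued against: thinned to the T47D total, the other libraries apart from MCF7 reached at most 0.637 times the genes of T47D. Receptor class or insulin is also argued against, since BT483, which shares both, had an olfactory receptor rate 0.0897 times the lower of T47D and MCF7. An even background of reads, as residual DNA may give, stays open: the lower of both lines had 3.98 times the median olfactory receptor rate of the other libraries and 6.55 times that of the second silent class, where a factor of at least 5 over olfactory receptors had been asked for and one under 2 would have spoken against it. A difference between the preparations of these lines was not tested.

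Of the 23 genes called higher in ER-positive lines, 0.0% had a T47D plus MCF7 count within 2 times the expected background. This background was taken from the olfactory receptor rate. The lowest ratio was 2.52, so at that rate background does not account for their whole level in these lines. Both lines were in the fit that called the genes, which favours high counts there, so the test is weak. MCF7 also had a higher rate over the second silent class (2.78 against 1.45 CPM per kb), so background may hold part of the counts of these genes. Depth stays open for most of them: thinned to the smallest total, 19 genes were higher, but 5 of the 23 had enough counts left to be tested, all of which passed, and 18 were not tested. Chance is argued against by splits of the 8 lines: the real split gave 33 genes, the highest other split 0, and 1 of the 35 splits, the real one, gave as many. For the TNBC count, 1 of 56 splits, the real one, gave as many as its 56 genes. The highest other was 49, from T47D, MCF7 and BT474 against the rest. These lines had the highest olfactory receptor rates of the 8 pooled libraries (2.61, 1.45 and 0.768 CPM per kb), and none of them is TNBC. The splits therefore do not set TNBC status apart from a difference in background. Added insulin as the whole cause is argued against, since BT474 had none and 100% of the 23 genes were higher in both its libraries than in any ER-negative line (TFF1 208 CPM or more against at most 1.04, PGR 351 against 11.5). As these genes were chosen with BT474 in the fit, the stricter test is on the 6 genes called higher without it, 5 of them among the 23. TFF1 and PGR are not among the 6. All 6 were higher in the same way. The margin was wide for TM4SF18-AS1 (779 CPM or more against at most 4.17) and narrow for CACNA1H (22.0 against 11.1) and CRMP1 (5.49 against 2.79). A part played by insulin, estrogen receptor activity and the origin of each line stay open.

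The third pattern is the run of genes around ERBB2 in the HER2-positive lines. A higher copy number of 17q12 predicts that neighbours outside the fixed list are higher too. The 41 such genes within 1 Mb of ERBB2 had a median log2 fold change of 1.91, and 38 were above 0. This lies at the 100th percentile of 10000 random sets of as many tested genes. None of the 41 passed the threshold (smallest edgeR adjusted p 0.0686). The random sets were not of neighbouring genes. A region whose genes move together for any reason could give this result, so it does not single out copy number. Reads shared between paralogs remain undecided. By a match of names, 25% of the 12 called genes had a tested paralog or pseudogene that rose too, between the bounds set beforehand. This hangs on ENSG00000218227, whose parent RPL19 was found by a sequence search that replaced a faulty name match after a first run. Not counted, it leaves 16.7%, under the lower bound of 20%. The match found no partner that rose for 9 of the 12, and none tested for 3 of these. It missed GSDMA, a tested paralog of GSDMB within 1 Mb of ERBB2, with a log2 fold change of 2.62 ± 0.95 (SE) that did not pass. Both shares may therefore be too low, and the 16.7% does not place the result under the bound. For the count of 12 genes chance is not excluded, since 4 of 28 pairs of lines gave as many, or 3 of 22 distinct fits, and 2 of 16 pairs with 1 line of each ER class; the highest other count was 117, from HS578T with MDAMB231 and, as the same fit, SKBR3 with HCC1143.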

How the results depend on the processing

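Leaving out T47D and MCF7, thinning and the background term were chosen after seeing the data; all other alternatives were fixed before. The called genes kept their signs, but they were picked for large changes in the same libraries that the alternatives refit. A steady sign was therefore largely fixed in advance and lends these genes no support. Of the 33, 56 and 12 genes called in the ER, TNBC and HER2 comparisons, those tested had the main direction in every alternative fit run (0 of 687, 1141 and 259 fitted values had the opposite sign), while the counts moved. ER calls (33) became 617 with DESeq2, 292 without a count filter, 10 with a stricter one, 14 with libraries summed per line, 16 with single libraries, 6 in limma-voom, 12 without abundant RNA genes, 11 in a robust fit, 78 with HER2 status as a term, 0 to 108 with a line left out and, in alternatives added after seeing the data, 2 without T47D and MCF7 and 17 with the background rate as a term. TNBC calls (56) became 656 with DESeq2, 357 without a filter, 108 with a stricter one, 18 in limma-voom, 19 to 336 with a line left out and, added later, 16 without T47D and MCF7, 90 thinned and 92 with the background rate. HER2 calls (12) became 59 with DESeq2, 24 without a filter, 0 in limma-voom (531 genes at an unadjusted p under 0.05), 6 with HER2 status alone, 0 to 82 with a line left out and, added later, 0 without T47D and MCF7 (645 at an unadjusted p under 0.05) and 20 with the background rate. BT474 against BT483 gave 7997 genes, 4499 with DESeq2 and 6065 to 7223 with a library left out. DESeq2 was run without the edgeR count filter, on 49728 genes in the ER comparison against 11595 in the main fit. Its counts therefore differ in both filter and test. Fewer lines or genes tested account for part of the changes in count by construction. Otherwise the cause was not tested.

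Lists past the threshold numbered 17, 13 and 10 (ER, TNBC, HER2). With an estimated correlation they were 0, 0 and 1, and in fry 0, 0 and 1. Without a count filter the TNBC lists were 23, and with a line left out the ranges were 15 to 18, 11 to 18 and 9 to 13. No RNA class passed in any alternative, with smallest p of 0.0286 for 4 against 4 lines. A single class at that p cannot pass the adjustment over classes, so the absence of calls says little. The SD between libraries of a line was 0.455 for BT474 and 0.324 for BT483; it was 0.285 and 0.185 over genes with at least 100 counts, and 0.488 and 0.359 with a pseudocount of 0.1 CPM. Upper-quartile scaling moved the median log2 fold change of all genes by 0.164 (ER) and -0.149 (TNBC). No paired analysis of the receptor comparisons was possible because their groups share no replicate numbers that mark a common culture or day; BT474 against BT483 with the kind of library as a block gave 7911 genes.

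Between BT474 and BT483, 25 of 7997 called genes had the opposite sign in an alternative, without a count filter or without the single BT474 library. In the receptor comparisons signs reversed in genes that had not passed. In the ER comparison ERBB2 (-0.59) became 0.79 in limma-voom, 0.83 with HER2 status as a term, -2.73 to 3.53 with a line left out (3.53 without SKBR3) and 0.26 without T47D and MCF7, and DDR2 (-4.76) was -5.39 to 0.12 with a line left out (0.12 without HS578T) and 0.23 with the background rate. In the HER2 comparison ESR1 (0.09) became -0.31 with HER2 alone, -0.15, -0.06 and -0.47 without HS578T, MDAMB231 and SKBR3, up to 0.73 without BT474, and -0.21 thinned. Without BT474, ANLN was -1.74, IDI1 -0.33, FDFT1 -0.81, ASNS -0.64 and MIAT 0.28. Without SKBR3, CDS1 was -0.58, SPINT1 -0.27, FAP 0.49 and COL1A1 1.72. The other ends of these leave-one-out ranges were 2.51 for ANLN, 0.70 for IDI1, 1.47 for FDFT1, 1.04 for ASNS, -1.62 for MIAT, 4.64 for CDS1, 4.69 for SPINT1, -0.97 for FAP and -5.33 for COL1A1. Without T47D and MCF7, IDI1 was -0.21, FDFT1 -0.09, ASNS -0.20 and MIAT 0.97. With HER2 alone FDFT1 was -0.08 and ASNS -0.03; thinned, IDI1 was -0.04; in limma-voom MIAT was 0.62 and FAP 0.43. COL1A1 (-0.02) was also 0.42 without a filter, 0.19 summed, 0.28 with single libraries, 0.08 without abundant RNA genes, 0.21 without HS578T and 0.02 without HCC1143. The vesicle formation list turned upward in the ER comparison without T47D and MCF7 (camera adjusted p = 0.7, and 0.00013 to 0.151 with a line left out), and the cholesterol list downward in the HER2 comparison without BT474 (camera adjusted p = 0.682, and down to 4.85e-08 without SKBR3). The cause was not tested.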

Other observations

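Several mRNAs that cells are known to send to their protrusions were abundant in the vesicles and varied widely between lines. KIF1C ranged from 1100 CPM in SKBR3 to 17200 CPM in HS578T, TRAK2 from 550 to 21200 CPM in the same lines, NET1 from 1180 CPM in T47D to 7900 CPM in pooled BT474, and RAB13 from 389 CPM in SKBR3 to 7320 CPM in HS578T. A hypothesis is that these mRNAs form a group that varies together between lines. It was tested on 4 further mRNAs of this class that were not chosen from these data, CYB5R3, DDR2, DYNLL2 and PKP4. Their mean correlation over the 8 lines with the mean of KIF1C, TRAK2, NET1 and RAB13 was 0.55, at the 99.6 percentile of 10000 random sets of like abundance, whose median was -0.02 and 95th percentile 0.35. The single correlations were 0.35 for CYB5R3, 0.68 for DDR2, 0.44 for DYNLL2 and 0.74 for PKP4. HS578T was the highest line for DDR2 and CYB5R3; without it, in a test chosen after seeing the data, the mean correlation over 7 lines was 0.47, at the 99.6 percentile of random sets, whose 95th percentile was 0.30. The result is consistent with a shared group, and whether it reflects the cells or their loading into vesicles could not be asked without cell libraries.

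The estimated share of counts that an even background at the olfactory receptor rate would give over the summed gene length was 35.0% in T47D, 19.5% in MCF7, 10.3% in pooled BT474 and 7.12% in HCC1143. The lowest were 1.02% in HS578T and 1.44% in single BT483. The estimate assumes that a background falls evenly over the genes and that olfactory receptor genes are silent. In MCF7 the second silent class had a higher rate (2.78 against 1.45 CPM per kb), and in T47D a similar one (2.56 against 2.61). HS578T also had a higher one (0.156 against 0.0763), and pooled BT474 a lower one (0.689 against 0.768). By that class the estimate for MCF7 would be higher and would stand above that for T47D.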
